A study of Mus musculus with 258 samples.

How the data were processed

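The series holds 258 mouse samples, of which 6 bulk RNA-seq libraries and 221 single cells are analysed here and 31 chromatin immunoprecipitation samples are not used here. Per the labels' protocols, bulk RNA came from sorted cells of dorsal pancreas, was selected for poly(A) and made into libraries with a strand-specific kit. Single cells were amplified with Smart-seq2, which copies whole transcripts without molecular identifiers, with ERCC spike-in RNA added. The submitters' processing notes name TopHat2 2.1.0, Bowtie2, HTSeq 0.6.0, DESeq 1.20.0 and the mouse build mm10. The version of Bowtie2, the strand setting of the counting and the annotation are not given in the sources used here, so a gene and its antisense partner cannot be told apart in these values. Reads of pseudogenes and of closely related families could be split between copies, and such genes are uncertain.

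The deposited tables hold whole-number counts per gene, made by the authors with HTSeq per the submitters' processing notes, without normalisation. RPKM values were deposited by the authors beside the counts, per library length-scaled values for single cells and 3 pooled columns for the bulk groups. The authors' pooled bulk RPKM stood at 0.932, 1.00 and 1.08 times the same quantity computed here from the counts. Each table lists 40916 entries, of which 92 are ERCC sequences and 40824 are genes. Gene symbols are those of the deposited tables, and 39864 of the gene identifiers were also found in a reference table of gene names. Chromosomes and coordinates come from a RefSeq gene table of assembly GRCm38. No mitochondrially encoded gene is listed (0 entries), so that list has no values. Every column was tied to 1 sample or pooled group, with 0 columns left over.

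Groups were taken from the titles and characteristics. The labels give bulk replicates numbers 1 and 2 and single cells a title number, but name no animal. Bulk libraries held 11957415 to 17760214 reads in genes. A gene without a read in a library has a floor of 3 counts, 0.169 to 0.251 CPM. Cells held a median of 708409 reads in genes and 3.91% ERCC reads. All 221 passed a minimum of 100000 reads in genes. Over a whole single-cell group the floor was 0.0575 to 0.0930 CPM. The median reads per cell were 608883 in WT Ngn3-low, 721848 in WT Ngn3-high, 734064 in deleted Ngn3-low and 738979 in deleted Ngn3-high cells.

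The following choices were fixed before the data were examined, apart from those named as later. Bulk counts were tested with edgeR 4.0.16 (R 4.3.3), with trimmed-mean factors, its expression filter, the quasi-likelihood test over all 6 libraries and Benjamini-Hochberg adjustment at 0.05 over 15684 genes. With 2 libraries per group, the 3 groups shared 1 estimate of the spread. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated instead, and with fry, adjusted over the lists. Of the calls made at the preset correlation, none held with an estimated correlation, where the lowest adjusted p from camera was 0.329. Stage patterns were compared with independent lists and with 20 simulations of unchanged groups that share the Ngn3-high libraries.

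Single-cell groups have 1 sample each and were not tested. Counts were summed per group and given as CPM with exact 95% Poisson intervals, and ratios as log2 with 1 CPM added to each side. Shares of cells at 10 CPM or more have exact Clopper-Pearson intervals. List medians were placed among 10000 random lists matched in 50 bins of expression, for members at 5 CPM or more in either group. Random lists draw genes independently, so genes that vary together can reach extreme percentiles without a difference between genotypes or gates. A percentile measures no spread between samples. The stage scores are means of log2(CPM + 1) over the 100 genes that rose or fell most in bulk.

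There were 26 lists: endocrine transcription factors, beta cell genes, non-beta islet genes, granule and exocytosis, trunk and duct, tip and acinar, Notch, cell division, cell cycle arrest, H3K27 methylation, H3K4 methylation with H3K27 acetylation, Hox, epithelial adhesion, migration and delamination, unfolded protein response, genes kept low in beta cells, immediate early genes, mitochondrially encoded genes, and markers of red blood cells, white blood cells, endothelium, mesenchyme, neural crest and glia, mesothelium, liver and intestine. Pancreatic cells also express some listed genes of other cell types, such as Egfl7, Ret and Vil1. The list of H3K4 methylation with H3K27 acetylation also holds genes of enzymes that remove such marks, such as Kdm1a and Hdac1. Text names come from a rule: 16 fixed genes, the 6 largest rises and falls with 10 CPM or more in the higher bulk group, and up to 4 changed members per list. For single cells the rule asked for 20 CPM and 25% of cells in the higher group, the same direction in every shared title number, and up to 3 members per list. Fixed genes were named whatever their values, and some genes that the rule covers are not reported here. A few genes outside the rule are marked as chosen after their values were seen.

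On simulated counts with 200 changed genes among 15684, the bulk test recovered 61.2%, 89.6% and 98.5% of genes changed 2-, 4- and 8-fold for Ngn3-high against Ngn3-low cells, with 18 false calls among 184. The recovery was 61.2%, 88.1% and 93.9% for Ins1-RFP positive against Ngn3-high cells (16 false of 178), and 50.7%, 82.1% and 92.4% against Ngn3-low cells (19 false of 169). For the single-cell ratios all simulated changes had the right direction, under counting noise alone.

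The alternatives tried were DESeq2 1.42.0, limma-voom, other size factors, other count filters, fits of only the compared groups, replicate number as a block, a test against a 1.5-fold change, and each library left out. For single cells they were means over cells, equal weights of title numbers, RPKM, trimmed-mean and ERCC scaling, other read minimums, thinning to 100000 reads, each title number left out, thresholds of 1 and 50 CPM, and scores of 50 or 200 genes. Total-count scaling of bulk counts, and restriction to title numbers whose cells of both genotypes carry Xist, were added after the data were seen. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.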

Results

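The series addressed how endocrine cells arise in the embryonic mouse pancreas and what the histone H3K27 demethylase Jmjd3, the product of Kdm6b, contributes to that choice of fate. Bulk RNA was sequenced from 3 sorted populations with 2 libraries each. Ngn3-low and Ngn3-high cells came from E13.5 pancreas (embryonic day) and were sorted by the strength of a green fluorescent reporter of Ngn3, the protein of Neurog3. Ins1-RFP positive cells came from E17.5 pancreas, and the labels describe them as nascent beta cells. RNA was also sequenced from 221 single cells of 4 groups, with 49 wild-type (WT) Ngn3-low cells, 59 WT Ngn3-high cells, 69 Jmjd3-deleted Ngn3-low cells and 44 Jmjd3-deleted Ngn3-high cells. Per the labels the deleted cells carried a floxed Jmjd3 gene and Pdx1-Cre, a recombinase active in pancreatic progenitors. The labels name no Cre for the WT cells, so effects of Cre and of the deletion cannot be told apart. The 31 chromatin immunoprecipitation samples are not analysed here.

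The bulk libraries held 11957415 to 17760214 reads in genes, with 18651 to 20063 genes carrying at least 1 read. The single cells held 380478 to 1949839 reads in genes, with a median of 708409. Bulk replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 13.6 in each group and 61.3 for Ins1-RFP positive cells, so all 6 libraries were counted separately. The labels do not say whether replicates came from separate litters, so bulk p-values measure only the spread between these libraries. Bulk values are mean normalised read counts (CPM) ± SD with n = 2, and bulk differences are log2 fold changes from edgeR.

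The step from Ngn3-low to Ngn3-high cells was examined first. Neurog3, the transcription factor that commits pancreatic progenitors to the endocrine fate, rose from 167 ± 24.6 to 1142 ± 81.2 CPM, and the genes of endocrine regulators and secretory granules rose with it. The cells were sorted by a reporter of Ngn3, so the rise of Neurog3 itself only checks the sort. Neurod1, a transcription factor that acts after Neurog3, rose from 2.72 ± 0.186 to 293 ± 51.4 CPM. The granule protein gene Chgb rose from 22.9 ± 6.71 to 8939 ± 688 CPM. All 30 cell division genes fell, as did the progenitor factor Sox9, which went from 266 ± 1.43 to 55.3 ± 4.99 CPM. Transcripts of macrophages and endothelial cells were also far lower in Ngn3-high cells. Of 15684 genes tested with edgeR, 4349 rose and 4729 fell, and 2251 of the rises and 3197 of the falls were at least 2-fold.

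All 19 endocrine transcription factors rose in Ngn3-high cells, and 19 rose when adjusted over the list alone. Neurod1 rose by 6.74 (SE 0.188, edgeR adjusted p = 2.83e-07) and Fev, a marker of endocrine progenitors, by 8.66 (SE 0.230, edgeR adjusted p = 2.83e-07). Pax4, a factor of the beta cell lineage, went from 21.5 ± 3.07 to 267 ± 49.9 CPM. Myt1, a zinc finger factor of endocrine progenitors, went from 6.02 ± 0.321 to 610.2 ± 39.4 CPM. Against other genes, camera gave an adjusted p = 5.81e-11 for the list, and an adjusted p = 0.329 with an estimated correlation. All 24 granule and exocytosis genes rose, with 24 when adjusted over the list alone. Chga rose by 4.99 (SE 0.327, edgeR adjusted p = 4.48e-06), and the prohormone convertase Pcsk1 rose by 5.92 (SE 0.243, edgeR adjusted p = 5.5e-07). Camera gave an adjusted p = 6.99e-12 for this list, and an adjusted p = 0.523 with an estimated correlation.

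Hormone genes and genes of mature islet function moved less uniformly in this step. Of 20 beta cell genes, 14 rose, 2 fell and 4 did not pass, with 15 rises and 2 falls when adjusted over the list alone (camera adjusted p = 6.47e-05, and adjusted p = 0.525 with an estimated correlation). The falls numbered 1 without Ngn3-low library 2 or Ngn3-high library 2. Papss2, which encodes an enzyme that makes the sulfate donor of the cell, rose by 3.97 (SE 0.205, edgeR adjusted p = 1.39e-06), to 169 ± 38.3 CPM. Ins1 averaged 24.7 CPM in Ngn3-low and 88.7 ± 3.13 CPM in Ngn3-high cells (log2 fold change 1.82, SE 0.870, edgeR adjusted p = 0.104). Ins1 passed when Ngn3-low library 1 was left out (4.98), when Ngn3-low library 2 was left out (0.92) and when Ins1-RFP positive library 1 or 2 was left out (both 1.82). Ins2 averaged 54.5 ± 66.7 and 159.8 ± 32.7 CPM (log2 fold change 1.55, edgeR adjusted p = 0.159) and passed at 4.45 without Ngn3-low library 1. Of 14 non-beta islet genes, 12 rose and 1 fell, the same as when adjusted over the list alone (camera adjusted p = 0.000105, and adjusted p = 0.525 with an estimated correlation). The glucagon gene Gcg rose from 245 ± 5.75 to 1012 ± 198 CPM, and Pou3f4, a factor of alpha cells, rose by 6.41 (SE 0.274, edgeR adjusted p = 6.04e-07). All 13 genes kept low in mature beta cells fell, with 13 when adjusted over the list alone (camera adjusted p = 5.9e-06, and adjusted p = 0.525 with an estimated correlation). Among them, Maf went from 366 ± 8.81 to 3.08 ± 0.709 CPM, and macrophages also express this gene.

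Most trunk and duct genes fell. In the trunk and duct list, 3 of 18 genes rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.00782, and adjusted p = 0.523 with an estimated correlation). Sox9 fell by 2.26 (SE 0.110, edgeR adjusted p = 1.03e-06) and Onecut1, a factor of early pancreatic epithelium, by 4.30 (SE 0.363, edgeR adjusted p = 1.87e-05). The tip and acinar list did not pass (camera adjusted p = 0.0816), with 7 of 19 genes falling and none rising, and 2 falling when adjusted over the list alone. The falls numbered 14, with 1 rise, without Ins1-RFP positive library 1 or 2 (camera adjusted p = 0.000221 and 0.000212), but 4 without Ngn3-low library 1 and 2 without either Ngn3-high library. Its member Cpa1, a digestive carboxypeptidase gene, fell from 274 ± 28.6 to 38.0 ± 2.01 CPM (edgeR adjusted p = 0.0369). Cpa1 no longer passed when any library of the compared groups was left out, with log2 fold changes of -2.73 and -2.95 without Ngn3-low library 1 or 2, and -2.81 and -2.89 without Ngn3-high library 1 or 2. Of 20 Notch pathway genes, 7 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.854). Their median was 0.00 and their mean -0.24. Hes1, the repressor induced by Notch signals, fell by 3.37 (SE 0.418, edgeR adjusted p = 0.000184) and the receptor gene Notch2 by 3.68 (SE 0.152, edgeR adjusted p = 5.5e-07), while the ligand gene Dll3 rose by 5.18 (SE 0.237, edgeR adjusted p = 7.83e-07).

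All 30 cell division genes fell, with 30 when adjusted over the list alone (camera adjusted p = 5.59e-13, and adjusted p = 0.523 with an estimated correlation). The proliferation marker Mki67 went from 576 ± 47.7 to 46.8 ± 6.86 CPM, and the mitotic kinase gene Cdk1 fell by 3.44 on the log2 scale. Of 12 cell cycle arrest genes, 8 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.153), and 1 fell when any library of the compared groups was left out. The stress-induced gene Gadd45a went from 50.2 ± 13.8 to 407 ± 44.1 CPM and the inhibitor gene Cdkn1a from 238 ± 37.6 to 588 ± 59.4 CPM.

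Among chromatin regulators, Kdm6b rose from 167 ± 8.29 to 333 ± 25.3 CPM (log2 fold change 0.99, SE 0.125, edgeR adjusted p = 0.000202). Ezh2, the methyltransferase that sets the H3K27 mark Jmjd3 removes, fell by 0.74 (SE 0.0966, edgeR adjusted p = 0.000259). Kdm6a, which encodes the related demethylase Utx, rose by 0.48 (SE 0.114, edgeR adjusted p = 0.00678) and did not pass without Ngn3-low library 2 (0.44). The list of H3K27 methylation genes did not pass as a whole (camera adjusted p = 0.606), with a median of 0.12, a mean of -0.00 and opposite directions from camera (up) and fry (down). Of 21 genes of H3K4 methylation and H3K27 acetylation, 14 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00782, and adjusted p = 0.523 with an estimated correlation), and none fell without Ngn3-low library 1 or 2 or Ngn3-high library 2. Kdm1a, a demethylase of H3K4, went from 213 ± 7.65 to 474 ± 8.54 CPM. As this list also holds genes of enzymes that remove marks, its direction does not show that of the marks. The reads were aligned to mouse build mm10, in which Kdm6b lies on chromosome 11 from 69398508 to 69420367 and Neurog3 on chromosome 10 from 62133090 to 62134763.

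Lists of epithelial adhesion (camera adjusted p = 0.245) and of migration and delamination (camera adjusted p = 0.699) did not pass. For migration the median was -0.36 and the mean -0.14, with camera down and fry up. Within these lists the neuronal tubulin gene Tubb3 went from 5.41 ± 0.425 to 195 ± 32.8 CPM, whereas Grhl2, a regulator of epithelial junctions, fell by 2.75 on the log2 scale and the mesenchymal factor Zeb2 by 5.14. The unfolded protein response list did not pass (camera adjusted p = 0.203), although Manf, a stress-induced protein of the endoplasmic reticulum, rose by 1.18 (SE 0.127, edgeR adjusted p = 8.04e-05). Of 16 immediate early genes, 1 rose and 11 fell, also when adjusted over the list alone (camera adjusted p = 0.00782, and adjusted p = 0.65 with an estimated correlation), and none rose without Ngn3-low library 2 or Ngn3-high library 1. Klf6 went from 782 ± 23.3 to 88.8 ± 28.4 CPM. The Hox list did not pass (camera adjusted p = 0.068, and 0.0460 from camera with replicate number as a block). It passed with camera without Ngn3-low library 1 (0.0473), Ngn3-high library 2 (0.00564) or Ins1-RFP positive library 1 or 2 (0.0174 and 0.00484).

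Markers of other cell types moved with these groups. All 11 white blood cell markers fell, with 11 when adjusted over the list alone (camera adjusted p = 2.28e-06, and adjusted p = 0.523 with an estimated correlation). Summed over the list they reached 2967 and 2388 CPM in the Ngn3-low libraries against 19.1 and 10.5 CPM in the Ngn3-high libraries. The receptor gene Csf1r of macrophages averaged 920.5 ± 134 CPM in Ngn3-low cells. The largest falls by rule were also macrophage genes without a read in Ngn3-high cells, with a floor of 3 counts over the group. Fcgr1 was at least 577-fold lower and Cd53 at least 575-fold lower. All 11 endothelial markers fell, with 11 when adjusted over the list alone and the same camera values as for white blood cells. Their sums were 472 and 507 CPM in Ngn3-low and 15.8 and 10.7 CPM in Ngn3-high cells, and Kdr fell by 6.55 (SE 0.201, edgeR adjusted p = 2.97e-07). The lists of red blood cells (camera adjusted p = 0.606), mesenchyme (0.245 from camera), neural crest and glia (0.806 from camera), mesothelium (0.313 from camera) and intestine (0.535 from camera) did not pass. The liver list (camera adjusted p = 0.0575) passed with camera at 0.0453 with replicate number as a block, at 0.0287 without Ngn3-low library 1, and at 0.00777 and 0.00701 without Ins1-RFP positive library 1 or 2. Zeb2, Maf and the immediate early genes fell alongside these markers. For neural crest the median was 0.05 and the mean -0.19, and for intestine the median was -0.27 and the mean -0.14 while camera gave up.

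**Figure D1:**
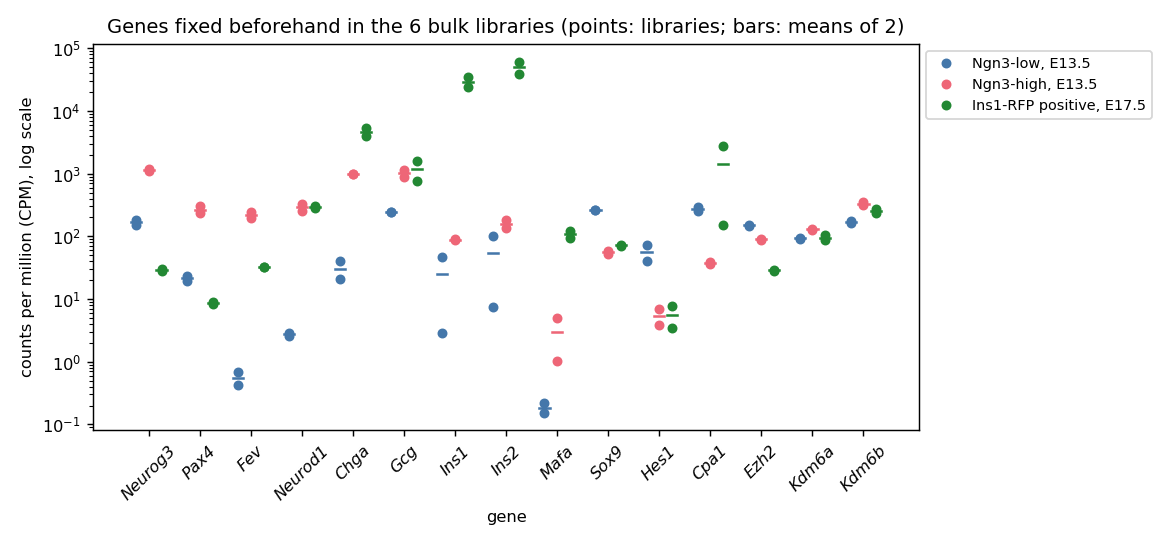
Normalised level (CPM, log axis) of 15 genes fixed in advance in each of the 6 bulk libraries, 1 point per library. Neurog3 and Pax4 stood highest in the Ngn3-high libraries, Ins1 and Ins2 in the Ins1-RFP positive libraries, and Sox9 and Hes1 in the Ngn3-low libraries.

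The step from Ngn3-high cells to Ins1-RFP positive cells was then compared, across which embryonic day and reporter changed together. The insulin genes rose strongly and several early endocrine factors fell. The later cells were sorted by an Ins1 reporter, so the rise of Ins1 itself only checks the sort. Ins1 reached 29303 ± 7892 CPM and Ins2 50482 ± 15527 CPM, while Neurog3 dropped to 29.3 ± 1.26 CPM, Pax4 to 8.70 ± 0.331 CPM and Fev to 32.6 ± 0.179 CPM. Of 14 unfolded protein response genes 12 rose, and of 21 genes of H3K4 methylation and H3K27 acetylation 14 fell, or 7 without Ins1-RFP positive library 2. Of 15684 genes tested with edgeR, 4087 rose and 3903 fell, and 2580 of the rises and 1738 of the falls were at least 2-fold. The balance depended on the scaling, with rises making up 44.8% of 8193 calls with total counts and 53.8% of 7910 with DESeq2 size factors. In this and the next comparison, where the rises and falls of a list are counted without a separate count, adjusting over the list alone gave the same counts. This does not cover lists whose counts are not given.

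Of 20 beta cell genes, 18 rose and none fell over all genes, with 18 rises and 1 fall when adjusted over the list alone (camera adjusted p = 6.03e-07, and adjusted p = 0.657 with an estimated correlation). Ins1 rose by 8.37 (SE 1.14, edgeR adjusted p = 0.000549) and Ins2 by 8.30 (SE 1.15, edgeR adjusted p = 0.000601). The granule zinc transporter gene Slc30a8 went from 9.71 ± 3.09 to 925 ± 132 CPM. Mafa, a transcription factor of mature beta cells, went from 2.96 ± 2.75 to 108 ± 18.6 CPM, with a log2 fold change of 5.28 (edgeR adjusted p = 6.41e-05) that was 4.47 without Ngn3-high library 1 and 6.71 without Ngn3-high library 2. Of 24 granule genes, 17 rose and 2 fell (camera adjusted p = 0.000389, and adjusted p = 0.737 with an estimated correlation), and 1 fell when any library of these groups was left out. Chga rose to 4618 ± 929 CPM, and Scg2 went from 65.4 ± 9.02 to 2831 ± 503 CPM. Chgb stood at 2534 ± 293 CPM.

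Of 19 endocrine transcription factors, 2 rose and 14 fell (camera adjusted p = 0.00053, and adjusted p = 0.657 with an estimated correlation), and 1 rose without Ngn3-high library 1. Neurog3 fell by 5.29 (SE 0.170, edgeR adjusted p = 1.04e-06) and Pax4 fell by 4.94 (SE 0.183, edgeR adjusted p = 1.28e-06). Neurod1 stood at 295 ± 9.65 CPM, a log2 difference of 0.01 (SE 0.135, edgeR adjusted p = 0.952). The list of non-beta islet genes did not pass (camera adjusted p = 0.204), but did without Ins1-RFP positive library 2 (camera adjusted p = 0.0216, down). Its member Gcg averaged 1189 ± 587 CPM (log2 difference 0.23, edgeR adjusted p = 0.542), passed at 0.66 without Ins1-RFP positive library 1, and turned to -0.38 without library 2. The somatostatin gene Sst rose from 5.32 ± 1.19 to 1105 ± 553 CPM, by 7.71 on the log2 scale, or 7.09 without Ins1-RFP positive library 2.

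Of 14 unfolded protein response genes, 12 rose and none fell (camera adjusted p = 6.05e-06, and adjusted p = 0.657 with an estimated correlation). Sdf2l1, part of a chaperone complex of the endoplasmic reticulum, went from 24.3 ± 0.426 to 332 ± 2.48 CPM, and the chaperone gene Hsp90b1 from 953 ± 39.6 to 3882 ± 161 CPM. Acinar transcripts also rose in this step, to 2582 and 40949 CPM in Ins1-RFP positive libraries 1 and 2. The unfolded protein response list did not follow this difference between libraries, with sums of 13883 and 13028 CPM. Of 16 immediate early genes, 12 rose, with 13 when adjusted over the list alone, and none fell (camera adjusted p = 0.000709, and adjusted p = 0.737 with an estimated correlation). Fos went from 507 ± 131 to 2456 ± 627 CPM. Among 30 cell division genes 16 rose and 5 fell, or 17 and 5 when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.737 with an estimated correlation). The falls numbered 3 without Ngn3-high library 2 or without Ins1-RFP positive library 2, and the call was lost without Ins1-RFP positive library 1 (camera adjusted p = 0.0729). Ccna2, a cyclin of S phase, went from 15.7 ± 1.09 to 45.4 ± 2.72 CPM. Cdkn1a fell by 3.72 (SE 0.173, edgeR adjusted p = 3.45e-06). The cell cycle arrest list did not pass (camera adjusted p = 0.815), with a median of 0.35 and a mean of -0.14.

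Ezh2 fell by 1.65 (SE 0.102, edgeR adjusted p = 1.12e-05), reaching 28.5 ± 0.526 CPM. Kdm6b stood at 254 ± 25.4 CPM, a log2 fold change of -0.39 (SE 0.124, edgeR adjusted p = 0.0288). This Kdm6b call was lost without Ngn3-low library 1 (-0.39), Ngn3-low library 2 (-0.40), Ngn3-high library 1 (-0.30) or Ins1-RFP positive library 2 (-0.29). Of 21 genes of H3K4 methylation and H3K27 acetylation, none rose and 14 fell, with 15 when adjusted over the list alone (camera adjusted p = 0.000389, and adjusted p = 0.657 with an estimated correlation). The falls numbered 9 without Ngn3-high library 1 and 7 without Ins1-RFP positive library 2. Kdm1a fell by 0.91 (edgeR adjusted p = 0.000316), and the deacetylase gene Hdac1 by 1.34 (SE 0.113, edgeR adjusted p = 4.46e-05). The H3K27 list did not pass (camera adjusted p = 0.515). Of 20 Notch pathway genes, 1 rose and 9 fell (camera adjusted p = 0.0153, and adjusted p = 0.737 with an estimated correlation), with 2 rises without Ngn3-high library 1. Without Ins1-RFP positive library 1 there were 3 rises and the call was lost (camera adjusted p = 0.0575). The ligand gene Dll1 fell by 2.31 (edgeR adjusted p = 4.71e-05), and Dll3 fell by 6.23 (edgeR adjusted p = 2.52e-06). Hes1 stood at 5.55 ± 2.91 CPM, a log2 difference of 0.01 (edgeR adjusted p = 0.985).

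Acinar transcripts differed between the Ins1-RFP positive libraries. Of 19 tip and acinar genes, 17 rose (camera adjusted p = 0.000389, and adjusted p = 0.737 with an estimated correlation), or 11 without either Ngn3-high library, and 2 fell without Ins1-RFP positive library 2. Their summed level was 2582 CPM in Ins1-RFP positive library 1 and 40949 CPM in library 2, against 267 and 240 CPM in the Ngn3-high libraries. Cpa1 rose by 5.24 (SE 1.10, edgeR adjusted p = 0.0047), was 6.17 without Ins1-RFP positive library 1 and 1.99 without library 2, and did not pass without Ngn3-high library 1 (5.20) or library 2 (5.29). Beside the rise of the immediate early genes, all 11 endothelial markers rose (camera adjusted p = 5.45e-05, and adjusted p = 0.657 with an estimated correlation), to sums of 66.1 and 81.5 CPM. White blood cell markers rose for 8 of 11 (camera adjusted p = 0.00128, and adjusted p = 0.737 with an estimated correlation), to sums of 82.1 and 142 CPM. Mesenchymal markers summed to 219 and 816 CPM (camera adjusted p = 0.0583, 0.0490 with replicate number as a block, and 0.000659 without Ins1-RFP positive library 1). The remaining lists did not pass with camera, and migration genes had a median of 0.21 and a mean of -0.01. Of these, genes kept low in beta cells and red blood cell markers passed with camera, up, without Ins1-RFP positive library 1 (adjusted p = 0.00752 and 0.000659), and adhesion passed, down, without Ngn3-high library 2 (0.0457). Red blood cell markers also passed without Ngn3-low library 1 (camera adjusted p = 0.0457).

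**Figure D2:**
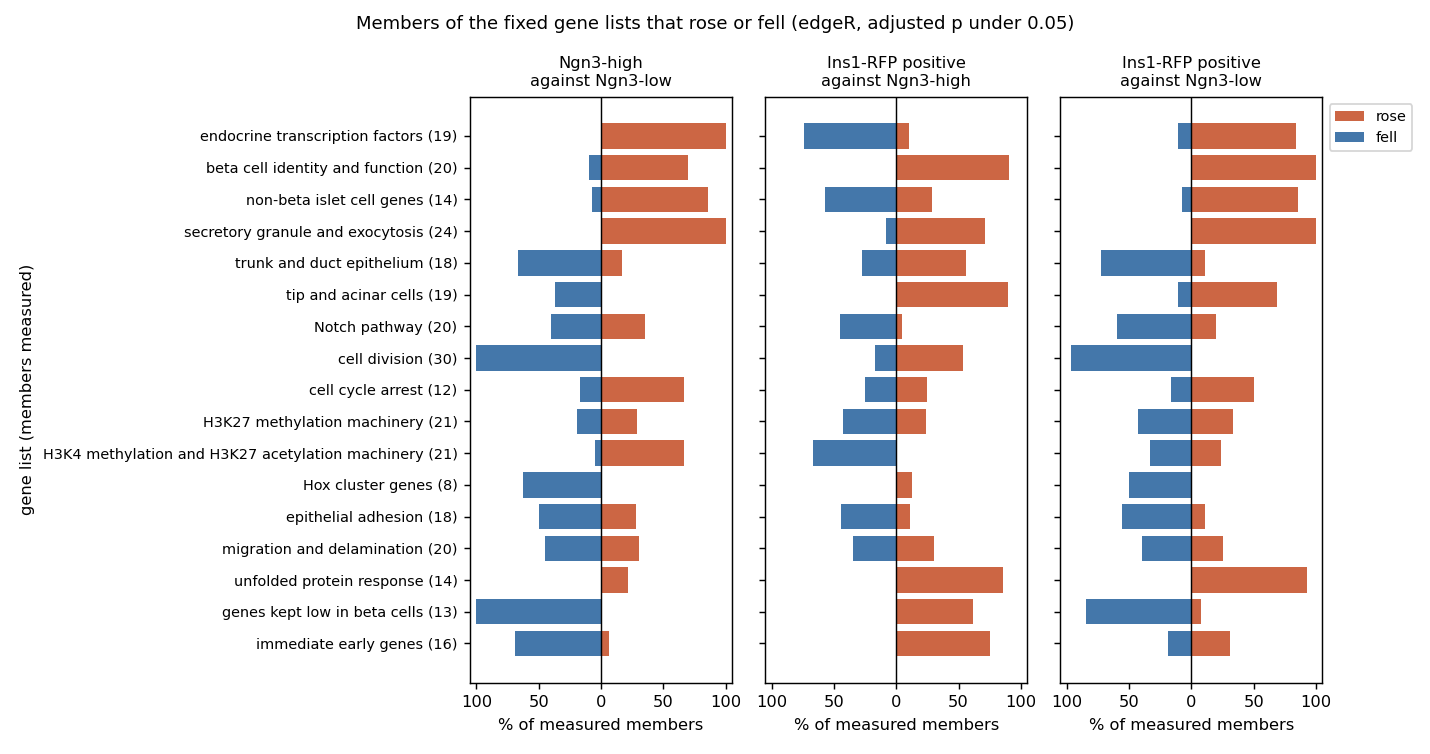
Percent of the measured members of 17 gene lists that rose (right) or fell (left) at an edgeR adjusted p under 0.05 in each of the 3 bulk comparisons. All 19 endocrine transcription factors and 24 granule genes rose, and all 30 cell division genes fell, from Ngn3-low to Ngn3-high cells.

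Between the ends of the course, Ins1-RFP positive cells were set against Ngn3-low cells. All 20 beta cell genes, all 24 granule genes and 13 of 14 unfolded protein response genes were higher in Ins1-RFP positive cells. Of 30 cell division genes 29 stood lower, and of 18 trunk and duct genes 13 stood lower and 2 higher. Slc30a8 was higher by 9.79 (edgeR adjusted p = 2.5e-07) and Pax6, a factor shared by islet cells, went from 6.05 to 563 ± 8.62 CPM. Of 15684 genes tested with edgeR, 4775 were higher and 5573 lower, and 3036 and 3615 of these by at least 2-fold. The higher genes made up 38.4% of 10586 calls with total counts and 50.6% of 10483 with only the 2 groups in the fit. Scaling by total counts in place of trimmed means moved the median of all genes by -0.166 in this comparison, and changes are stated relative to the trimmed-mean scale.

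All 20 beta cell genes rose, with 20 when adjusted over the list alone (camera adjusted p = 7.07e-10, and adjusted p = 0.465 with an estimated correlation), and all 24 granule genes rose (camera adjusted p = 2.33e-12, and adjusted p = 0.465 with an estimated correlation). Ins1 rose by 10.19 (SE 1.23, edgeR adjusted p = 0.000127), by 13.34 without Ngn3-low library 1 and by 9.29 without Ngn3-low library 2. Of the endocrine transcription factors, 16 of 19 rose and 2 fell, with 16 and 3 when adjusted over the list alone (camera adjusted p = 4.29e-05, and adjusted p = 0.465 with an estimated correlation). Neurod1 rose by 6.75 (SE 0.188, edgeR adjusted p = 1.82e-07), whereas Neurog3 fell by 2.51 (edgeR adjusted p = 2.64e-06) and Pax4 by 1.31 (edgeR adjusted p = 0.000239). Among 14 unfolded protein response genes, 13 rose (camera adjusted p = 6.21e-06, and adjusted p = 0.465 with an estimated correlation). Non-beta islet genes rose for 12 of 14 and fell for 1 (camera adjusted p = 0.00175, and adjusted p = 0.659 with an estimated correlation), and fell for 2 without Ins1-RFP positive library 2. The tip and acinar list did not pass (camera adjusted p = 0.0548), but did without Ins1-RFP positive library 1 (camera adjusted p = 2.63e-06, up). Cpa1 differed by 2.40 (SE 0.962, edgeR adjusted p = 0.0548), passed at 3.32 without Ins1-RFP positive library 1 and turned to -0.85 without library 2.

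Trunk and duct genes fell for 13 of 18 and rose for 2, with 14 and 2 when adjusted over the list alone (camera adjusted p = 0.00936, and adjusted p = 0.465 with an estimated correlation). Sox9 fell by 1.89 (edgeR adjusted p = 2.01e-06). Cell division genes fell for 29 of 30 (camera adjusted p = 1.83e-10, and adjusted p = 0.465 with an estimated correlation). Epithelial adhesion genes fell for 10 of 18 and rose for 2 (camera adjusted p = 0.0471, and adjusted p = 0.465 with an estimated correlation), a call that camera lost with replicate number as a block (adjusted p = 0.0559), without Ngn3-low library 1 (0.0547) and without Ins1-RFP positive library 2 (0.102). Notch genes fell for 12 of 20 and rose for 4 without passing as a list (camera adjusted p = 0.0548), and passed with camera without Ngn3-low library 2 (0.039) or Ins1-RFP positive library 1 or 2 (0.0305 and 0.0227). Genes kept low in beta cells fell for 11 of 13 and rose for 1 (camera adjusted p = 0.00145, and adjusted p = 0.659 with an estimated correlation), and none rose without Ngn3-low library 2. Rest, a repressor of neuronal genes, went from 165 to 7.98 CPM. Ezh2 fell by 2.38 (edgeR adjusted p = 5.79e-07), Kdm6b rose by 0.60 (SE 0.124, edgeR adjusted p = 0.00282), and Kdm6a differed by 0.03 (edgeR adjusted p = 0.82). The H3K27 list (camera adjusted p = 0.835) and the H3K4 list (camera adjusted p = 0.99, median -0.00, mean -0.05, up by camera and down by fry) did not pass. White blood cell and endothelial markers again fell for 11 of 11 each, with camera adjusted p = 0.00018 and 0.000547, and both with an adjusted p = 0.594 with an estimated correlation. Migration genes (camera adjusted p = 0.835) had a median of -0.53, a mean of -0.15 and fry up. Neural crest genes (camera adjusted p = 0.96) had a median of 0.85 and a mean of -0.47, and the remaining lists did not pass with camera. Of these, red blood cell and mesenchymal markers passed with camera, up, without Ins1-RFP positive library 1 (adjusted p = 0.00664 and 0.00993), and intestine, up, without Ngn3-low library 2 (0.039). Hox genes passed with camera, down, without Ngn3-high library 2 (adjusted p = 0.0416) or Ins1-RFP positive library 2 (0.013), and liver markers, down, without the latter (0.0104).

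Genes were also grouped by their direction in the 2 consecutive steps. A rise followed by a fall was shown by 1642 genes and a fall followed by a rise by 1745 genes, while 940 rose in both and 752 fell in both, or 489 without Ngn3-low library 1. Independent lists of these sizes would share 1082, 1232, 1133 and 1177 genes, and 20 simulations of unchanged groups gave 0. The simulations leave out the real changes, so this 0 does not measure how much the shared libraries add. Both steps use the Ngn3-high libraries, which are too few to split, so part of any excess could come from them. Markers of other cell types also fell and then rose. All 11 endothelial markers fell and then all 11 rose, and of 11 white blood cell markers 11 fell and then 8 rose. Of 12 mesenchymal markers none passed in the first step. How many of the 1745 genes reflect other cell types in the sorts was not counted. Among genes that peaked in Ngn3-high cells were Nhlh1, a neuronal helix-loop-helix factor (0.579 ± 0.172, 100.3 ± 4.06 and 0.476 ± 0.103 CPM across the stages), and the peptide hormone gene Cck (1.34 ± 0.148, 135 ± 30.2 and 1.56 ± 0.681 CPM). Dll3 followed the same course (1.42 ± 0.280 and 52.6 ± 5.48 CPM in the first 2 populations) and fell by 6.23 in the next step. Nhlh1 was chosen after its values were seen.

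**Figure D3:**
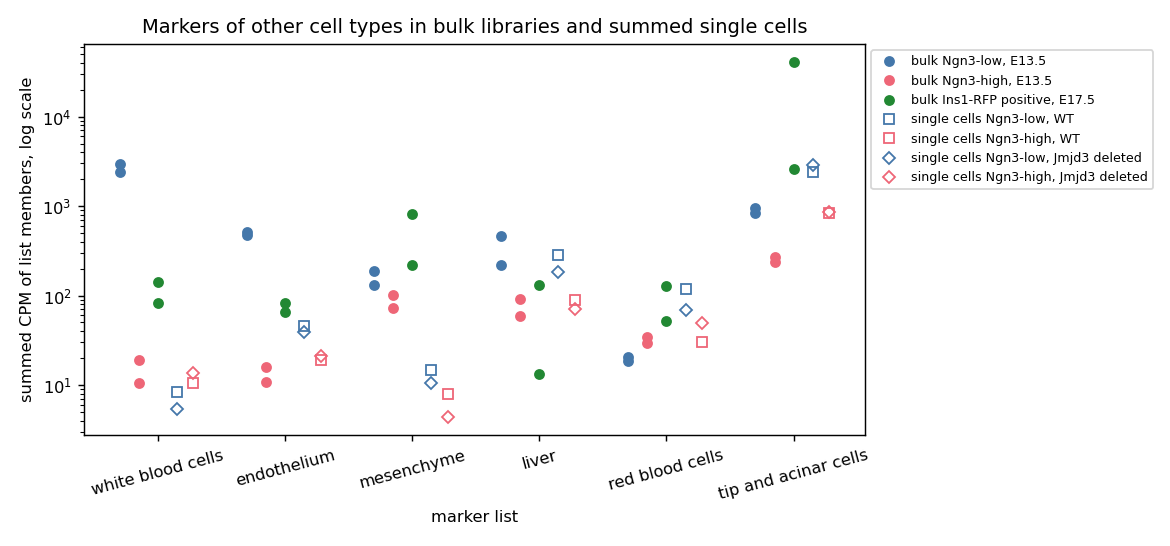
Summed level (CPM, log axis) of the markers of 6 other cell types in each bulk library and in the summed single cells of each group. White blood cell markers reached 2967 and 2388 CPM in the bulk Ngn3-low libraries and 8.44 CPM in the summed WT Ngn3-low single cells.

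In the single cells, which the labels do not tie to animals, each group counts as 1 sample and no difference has a replicate check. Values are summed counts as CPM with exact 95% Poisson intervals, and intervals and floors cover counting error only. The cells carry a number in their titles, 1 to 6, whose meaning is not given. Ratios within numbers shared by both groups are given beside part of the pooled ratios. Numbers 3 and 4 hold only WT Ngn3-low cells (7 and 14), number 2 only Ngn3-low and number 6 only Ngn3-high cells. Pooled ratios can thus compare unlike sets of numbers, and some ratios within numbers rest on as few as 5 cells of a group. Deleted cells were checked first for Kdm6b. It stood at 131 CPM (interval 127 to 135) in WT Ngn3-low, 265 CPM (260.2 to 269.9) in WT Ngn3-high, 55.5 CPM (53.5 to 57.6) in Jmjd3-deleted Ngn3-low and 107 CPM (103 to 110.3) in Jmjd3-deleted Ngn3-high cells. The gene counts include exons outside the deleted part, and reads from those check nothing.

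Single Ngn3-high cells had more reads of endocrine factors and granule genes than Ngn3-low cells, and fewer of division and trunk genes. In WT cells Chgb stood at 7895 against 7.48 CPM, Neurod1 at 774 against 0.216 CPM and Fev at 388 against 0.124 CPM. Hes1 went the other way, with 0.574 CPM in Ngn3-high and 171 CPM in Ngn3-low cells, and Sox9 stood at 82.6 against 1151 CPM. Among Jmjd3-deleted cells Chgb reached 7193 CPM and Cck 804 CPM in the Ngn3-high group. Kdm6b was higher in Ngn3-high cells in both genotypes, with log2 ratios of 1.01 in WT (0.83 and 1.72 within numbers 1 and 5) and 0.93 in Jmjd3-deleted cells (0.80 and 1.81).

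All 19 endocrine transcription factors were higher in WT Ngn3-high cells, with a median log2 ratio of 5.03, and all 18 measured in deleted cells, with a median of 5.14. All 21 granule genes were higher in WT (median 4.26) and all 22 in deleted cells (median 4.98). Cell division genes were lower for 30 of 30 in both genotypes, with medians of -3.02 in WT and -4.01 in deleted cells. The mitotic kinase gene Aurkb had no read in the 59 WT Ngn3-high cells and stood at 88.3 CPM in WT Ngn3-low cells. By the number of cells, up to 5.08% of WT Ngn3-high cells could still express it, so no fold is given. Trunk genes were lower for 11 of 15 in WT (median -1.41) and 12 of 15 in deleted cells (median -2.68). Epithelial adhesion genes were lower for 12 of 18 and 14 of 18, with medians of -1.04 and -0.93. Genes kept low in beta cells were lower for 10 of 10 and 9 of 9, with medians of -2.38 and -2.78. These medians lay at percentile 0.01 or lower, or at 100, of 10000 matched random lists, and each had the same sign within numbers 1 and 5. Here and below, percentiles treat genes as independent, describe these cells only and are no test. Immediate early genes were higher for 9 of 12 in WT (median 1.06) and 8 of 12 in deleted cells (median 0.79), opposite to the bulk libraries, with Btg2, an antiproliferative gene, at 737 against 44.9 CPM in WT.

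The tip and acinar list had a pooled median of -4.05 in WT cells, but medians of -0.05 and 0.15 within the shared numbers 1 and 5. Cpa1 likewise stood at 12.8 against 988 CPM, while its ratios within numbers 1 and 5 were above 0. In deleted cells the list's median was -4.65, with -4.46 and -4.00 within numbers 1 and 5. White blood cell markers summed to 8.44 CPM in WT Ngn3-low, 10.5 CPM in WT Ngn3-high, 5.35 CPM in deleted Ngn3-low and 13.48 CPM in deleted Ngn3-high cells. Across the 8732 genes at 20 CPM or more in either gate, the WT single-cell ratios correlated with the bulk log2 fold changes at r = 0.901 and rho = 0.838, and across 8720 genes those of deleted cells at r = 0.900 and rho = 0.847. Genes are not independent replicates, so no p is given. Among them, 2186 were called at 2-fold in bulk, and 97.4% of these had the same sign in WT cells. Most of the 2251 rises and 3197 falls called at 2-fold in bulk lay below that level in the WT single cells and are not in this share. Relative to the spike-ins the median of all genes shifted by -0.339 in WT and -0.169 in deleted cells, and by -0.114 between genotypes in Ngn3-low cells.

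The question of Jmjd3 was put to Ngn3-high cells of both genotypes. In Jmjd3-deleted cells Neurog3 stood at 1735 CPM (interval 1721 to 1749.7) against 1256 CPM (1246 to 1267) in WT, and Neurod1, which acts after it, stood lower. Neurod1 stood at 542 CPM (534 to 549.9) against 774 CPM (766 to 782). The log2 ratios of Neurog3 were 0.57, 0.35 and 0.45 within numbers 1, 5 and 6, and those of Neurod1 -0.35, -0.85 and -1.01. Kdm6b itself had a pooled log2 ratio of -1.30, with -1.44, -0.89 and -1.84 within the numbers. Chga, at 729 against 749 CPM, had a pooled log2 ratio of -0.04, with -0.33, 0.95 and -1.21 within the numbers, and Ezh2 a ratio of 0.03.

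Neurod1 was at 10 CPM or more in 86.4% of cells of either genotype. Of 19 endocrine transcription factors, 8 stood higher and 11 lower in deleted cells, with a median of -0.19, at percentile 0.01 of random lists. The list's medians within numbers 1, 5 and 6 were -0.20, 0.04 and -0.65. Runx1t1, a transcriptional corepressor, was lower by 0.72 and had the same direction in every number. Fev was lower by 0.37, from 388 to 299 CPM, and Pax4 by 0.29, with number 5 at 0.08. Granule genes stood lower for 15 of 22 (median -0.09, percentile 3.05), with 0.03, 0.27 and -1.16 within numbers, and Pcsk1 at 200.5 against 321 CPM. Immediate early genes were also lower in number 6 (median -0.07, percentile 14.6), with -0.08, -0.09 and -1.07 within numbers. Beta cell genes stood higher for 9 of 12 (median 0.43, percentile 100), with -0.16, 0.81 and -0.08 within numbers. Pdx1, a pancreatic and beta cell factor, stood at 219.6 against 169 CPM, with the same direction in every number. The labels name Pdx1-Cre for the deleted cells only, and its part in this difference was not tested. Non-beta islet genes, which include Sst, read in nearly every cell of number 5, had a median of -0.27 (percentile 0.68), with 0.14, -0.55 and -0.55 within numbers.

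Notch pathway genes stood higher for 11 of 16 in deleted Ngn3-high cells (median 0.28, percentile 98.8), with 0.01, 0.23 and 0.82 within numbers. Rbpj, the DNA-binding partner of Notch receptors, stood at 96.8 against 56.3 CPM. Cell division genes stood lower for 20 of 25 (median -0.42, percentile 0.01), with -0.89, -0.92 and 0.33 within numbers. Cell cycle arrest genes stood higher for 8 of 10 (median 0.19, percentile 98.5), with 0.28, 0.07 and 0.21 within numbers and -0.06 for the pooled median without number 1. The inhibitor gene Cdkn1c stood lower, at 101 against 182 CPM. Migration genes stood higher for 8 of 13 (median 0.32, percentile 99.2; 0.18, 0.15 and -0.02 within numbers), with the matrix protein gene Fn1 at 115 against 65.9 CPM. The H3K27 list (median 0.06, percentile 66.9), the H3K4 list (0.00, percentile 37.6), trunk genes (0.05, percentile 63.2), the unfolded protein response (0.07, percentile 80.5) and adhesion genes (0.07, percentile 81.9) lay within the range of random lists. By size, the peptidase gene Enpep stood highest on an autosome, at 21.1 against 0.299 CPM, and the nuclear receptor gene Esrrg lowest, at 10.2 against 42.4 CPM.

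The genotypes also differed in reads of sex-linked genes. Xist, expressed from the inactive X, stood at 566 CPM in deleted and 103 CPM in WT Ngn3-high cells, and the Y-linked gene Uty at 1.36 against 50.4 CPM. All deleted Ngn3-high cells carried Xist, whereas WT cells of numbers 1 and 6 carried Y-linked reads and those of number 5 carried Xist in 100% of cells. The 265 X-linked genes had a median log2 ratio of 0.01 against 0.03 for autosomal genes.

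**Figure D4:**
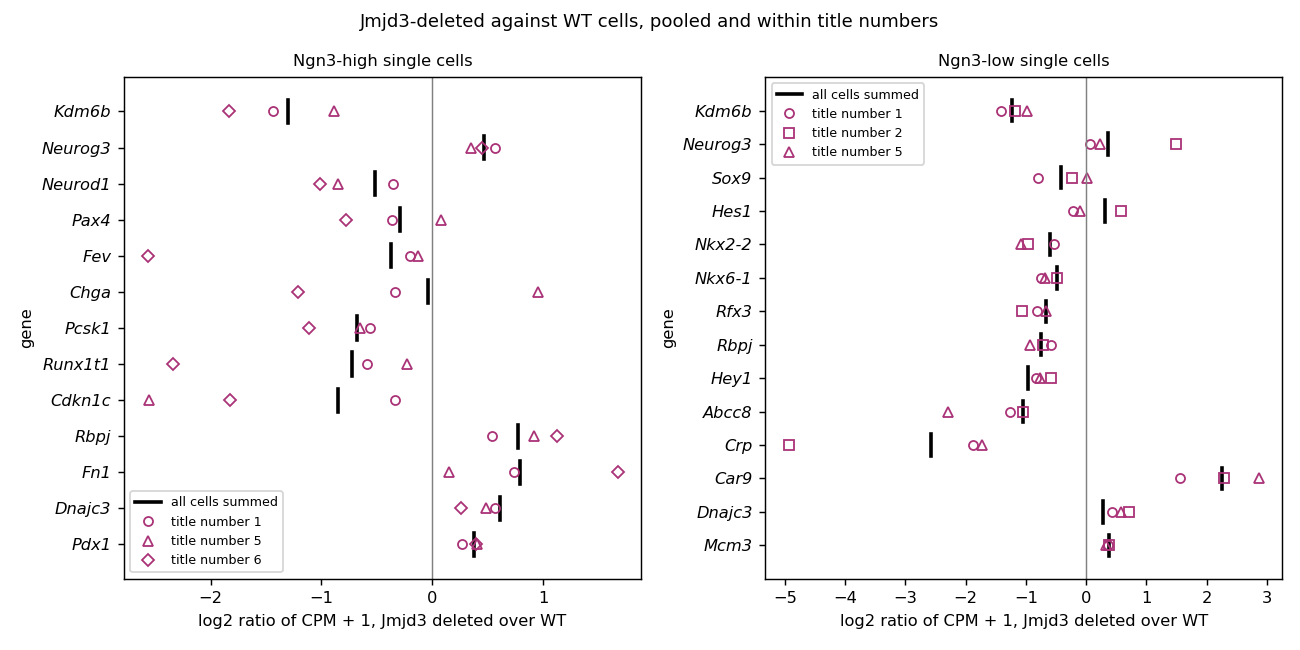
Log2 ratio of Jmjd3-deleted to WT cells (CPM with 1 CPM added) for 13 genes in Ngn3-high and 14 in Ngn3-low cells, pooled and within each title number. Kdm6b lay below 0 in every number of both gates, and Neurog3 above 0.

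In Ngn3-low cells several endocrine regulators, at their low levels there, and Rbpj stood lower in the deleted group. Nkx2-2, an islet factor, stood at 40.8 CPM (39.0 to 42.5) in deleted and 62.4 CPM (59.7 to 65.2) in WT cells. Rfx3 stood at 117 against 187 CPM, Nkx6-1 at 65.7 against 92.1 CPM and Rbpj at 50.7 against 85.5 CPM. Kdm6b had a log2 ratio of -1.23, with -1.41, -1.18 and -0.98 within numbers 1, 2 and 5. Neurog3 stood at 90.8 against 70.3 CPM (log2 ratio 0.36), with 0.06, 1.49 and 0.22 within numbers.

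Endocrine transcription factors stood lower for 7 of 9 in deleted Ngn3-low cells (median -0.48, percentile 0.02), with -0.53, -0.48 and -0.66 within numbers 1, 2 and 5. Abcc8, a subunit of the beta cell potassium channel, stood at 55.1 against 115 CPM. The beta cell list stood lower for 7 genes and higher for 3 (median -0.21, percentile 7.37), with -0.23, 0.51 and 0.23 within numbers 1, 2 and 5. Notch genes had a median of -0.07 (percentile 16.6), with -0.22, -0.48 and 1.03 within numbers, while Hey1, a Notch target, stood at 10.7 against 21.9 CPM. Genes of H3K4 methylation and H3K27 acetylation stood lower for 15 of 21 (median -0.23, percentile 0), with 0.11, -0.21 and -0.09 within numbers 1, 2 and 5 and a median of 0.03 without number 2. Unfolded protein response genes stood higher for 12 of 13 (median 0.23, percentile 98.7), with 0.32, 0.66 and -0.30 within numbers. Dnajc3, a cochaperone, stood at 165 against 136 CPM. Cell division genes stood lower for 23 of 30 (median -0.27, percentile 0), with -1.74, -0.40 and 0.92 within numbers, while the replication gene Mcm3 stood higher, at 292 against 225 CPM. Tip and acinar genes stood higher for 12 of 14 (median 0.38, percentile 100), with 4.31, 0.53 and 3.02 within numbers. Cpa1 stood at 1086 against 988 CPM and was at 10 CPM or more in 36.2% of deleted and 42.9% of WT cells. Trunk genes stood lower for 9 of 15 (median -0.06, percentile 2.09), with -0.09, 0.06 and -0.04 within numbers, and Sox9 at 858 against 1151 CPM but a ratio of 0.02 in number 5.

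Liver markers moved with these groups, all 4 measured standing lower in deleted Ngn3-low cells (median -0.50, percentile 1.12; -0.58, -0.42 and -0.70 within numbers), with Serpina1b at 73.5 against 145 CPM. Red blood cell markers stood lower for 5 of 5 (median -0.84, percentile 0.11), at sums of 69.8 against 118.5 CPM, but had medians of 1.33, -1.17 and 0.00 within numbers 1, 2 and 5. By size, Car9, a carbonic anhydrase gene, stood highest at 27.1 against 4.89 CPM, and Crp, an acute-phase protein gene, was the lowest autosomal gene at 24.3 against 149.8 CPM. Crp was at 10 CPM or more in 24.6% of deleted and 71.4% of WT cells. Deleted cells carried Xist in 98.6% of cells, and WT cells in 40.8%.

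A stage score, the mean log2(CPM + 1) of the 100 genes with the largest bulk rise, averaged 0.18 ± 0.14 (SD over 49 cells) in WT Ngn3-low and 3.61 ± 1.37 (59 cells) in WT Ngn3-high cells. Deleted cells averaged 0.16 ± 0.08 (69 cells) and 3.53 ± 1.17 (44 cells). The genotypes differed by -0.08 in Ngn3-high cells, with 0.30, 0.05 and -1.23 within numbers 1, 5 and 6, and by -0.01 in Ngn3-low cells, with -0.10, -0.04 and -0.05 within numbers 1, 2 and 5. The score of the 100 largest bulk falls differed by -0.09 between gates in WT (-0.09 and -0.02 within numbers 1 and 5) and by -0.00 in deleted cells, and 94 of these 100 genes lay under 1 CPM in the summed Ngn3-low single cells.

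**Figure D5:**
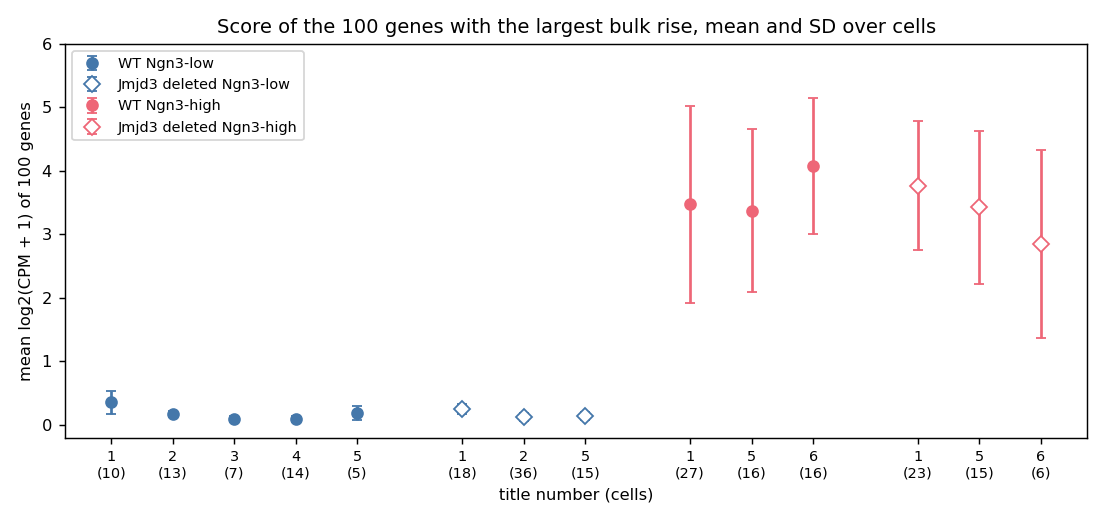
Mean of the stage score over cells, mean log2(CPM + 1) of 100 bulk rise genes, for each group and title number, with bars of 1 SD over cells. Ngn3-high cells averaged 3.61 in WT and 3.53 in Jmjd3-deleted cells.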

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

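All tests in this part were chosen only after the result was seen. ERCC spike-in reads, which the bulk protocol does not mention, numbered 13 in bulk Ngn3-low library 1 and 22 in Ngn3-high library 1, with 2 in Ngn3-high library 2 and 0 in the other 3 libraries.

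Among 95 genes examined, 5 differed between Jmjd3-deleted and WT cells in opposite directions in the 2 gates, in every title number both genotypes share. The 95 may include genes too low to compare in both gates. The naming rule for single cells already asked for the same direction in every shared title number. How many such genes would arise by chance was not computed, so the count of 5 shows no excess. These differences were not tested. Rbpj stood higher in deleted Ngn3-high cells (log2 ratio 0.77) and lower in deleted Ngn3-low cells (-0.74), a difference of 1.51. Rfx3, a ciliary and islet factor, had ratios of 0.12 and -0.67, a difference of 0.79. Rbbp5, a subunit of H3K4 methyltransferases, differed by 0.60 (0.30 against -0.31), and the antiproliferative gene Btg1 by 0.52 (0.19 against -0.33). Sec61b, part of the translocon, went the other way by -0.39 (-0.07 against 0.31).

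Sst, the somatostatin gene, was read in nearly every cell of title number 5. It was at 10 CPM or more in 50 of 51 cells there and in 0 of 170 cells of the other numbers (limit 1.76%), and no other gene had this pattern. Somatostatin cells in the sort would give high reads in a few cells, but 95% of the Ngn3-low cells of that number (19 of 20) carried Sst and none exceeded 106 CPM, which argues against them. The group levels of 73.9, 58.2, 53.5 and 74.5 CPM lay within 1.39-fold of each other whatever the gate or genotype, which is what contamination of the wells with Sst sequence could give. Where such material came from was not tested.

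Neurog3 stood higher and Neurod1 and Kdm6b lower in Jmjd3-deleted Ngn3-high cells. Cells were weighted to the same stage score to ask about a shift along the course from Ngn3-low to endocrine cells. After this, 2 of 2 genes (Neurog3 and Neurod1) kept most of their log2 ratio (0.48 and -0.47, against 0.49 and -0.53 before). The mean scores of the genotypes differed by only -0.08 before, so the weighting could change little. A shift that this score does not measure stays open, and within number 6 the score differed by -1.23. In number 5, where the cells of both genotypes carry Xist, 3 of 3 genes kept their direction beyond 0.3. Kdm6b is the deleted gene itself, so only Neurog3 and Neurod1 bear on the sex of the embryos. Number 5 is also the number with Sst reads in nearly every cell. With only 1 number that has Xist in both genotypes, an effect of the sex of the embryos cannot be told apart from one of the genotype. Within numbers 1, 5 and 6 the ratios had the same direction (Neurog3 0.57, 0.35 and 0.45, Neurod1 -0.35, -0.85 and -1.01, Kdm6b -1.44, -0.89 and -1.84). The deletion itself stays open as a cause, as does Cre, which the labels name only for the deleted cells.

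White blood cell and endothelial transcripts were abundant in the bulk Ngn3-low libraries. Over 118 single Ngn3-low cells the 2 lists summed to 6.53 and 41.3 CPM, at most 8.76% of the bulk sums, which argues against expression by the Ngn3-low epithelial cells as the main origin. The lowest ratio of bulk to single cells was 11.4, for endothelium, and 365 for white blood cells, which is what cells of these types in the bulk sort could give. Egfl7 of the endothelial list is also read in the single Ngn3-low cells. Whether the bulk and the single-cell sorts used the same gates is not given and stays open.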

How the results depend on the processing

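Total-count scaling of bulk libraries and the restrictions to title numbers with Xist in both genotypes were chosen only after the result was seen; the other settings were planned. Most values kept their direction and their side of the threshold: 1626, 1651 and 1721 values of the 3 bulk comparisons, against 58, 59 and 40 that no longer passed. Against a 1.5-fold change, 2387 genes rose from Ngn3-low to Ngn3-high, 2401 rose and 1765 fell from Ngn3-high to Ins1-RFP positive, and 3168 rose from Ngn3-low to Ins1-RFP positive, because a stricter hypothesis passes fewer genes. At 1.5-fold the stage patterns rise-rise, rise-fall, fall-rise and fall-fall held 377, 648, 930 and 189 genes, and at 2-fold 393, 640, 1077 and 202. Without single libraries the fall-fall count ranged from 489 to 774. DESeq2 shared 8567 of 9078, 7249 of 7990 and 9627 of 10348 calls with edgeR in the same direction. The bulk numbers pair nothing known: same-numbered deviations correlated at 0.0671, 0.0930 and 0.0303, and a replicate block moved the calls from 9078 to 9367, 7990 to 8171 and 10348 to 10564. With that block 32 of 33 camera calls held and 3 were gained. Fry kept 32 calls and gained 10. The sign of some genes turned, and the cause was not tested. In Ins1-RFP positive against Ngn3-high cells, Neurod1 was -0.0722 with total counts and -0.14 to 0.19 without single libraries, Gcg -0.38 to 0.66 without single libraries, and Hes1 -0.0894 with limma-voom, -0.0671 with total counts and -0.65 to 0.50 without single libraries. In Ins1-RFP positive against Ngn3-low cells, Kdm6a was -0.14 with total counts and -0.0933 to 0.16 without single libraries, and Cpa1, at 2.40 with all libraries, -0.85 to 3.32. In single cells, leaving out title numbers gave ranges across 0 for cell cycle arrest between genotypes in Ngn3-high (-0.0622 to 0.23), H3K4 genes between genotypes in Ngn3-low (-0.26 to 0.0341), Notch (-0.0920 to 0.71) and red blood cell markers (-2.46 to 0.96) between gates of deleted cells, Syt13 in Ngn3-high (-0.15 to 0.0497) and Bicc1 in Ngn3-low cells (-0.31 to 0.0415). ERCC scaling gave -0.13 for H3K27 genes between gates of deleted cells. The rise score difference between gates was 3.65 with 50 genes, 3.04 with 200, 3.37 thinned to 100000 reads, 2.65 from RPKM, 3.50 at 500000 reads and 3.26 to 3.59 without single numbers in WT. In deleted cells it was 3.04 with 200 genes, 2.59 from RPKM, 3.17 with equal weights and 3.13 to 3.47 without single numbers. Between genotypes in Ngn3-low it was -0.0555 at 500000 reads and -0.0456 to 0.0233 without single numbers. The fall score between gates of deleted cells was -0.0436 with 200 genes, 0.00711 with equal weights and -0.00790 to 0.0109 without single numbers. Without a library, the lone library of its group is assumed to vary like the others. The minimum of 100000 reads removed no cell, so dropping it changed nothing. Depth leaves single-cell genes below 0.0575 to 0.0930 CPM per group unmeasured. Shares rest on 5 to 36 cells per number and group and have wide intervals.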

Other observations

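All tests in this part were chosen only after the result was seen, and the genes named here were chosen after their values were seen. The bulk falls and the single cells differed more than the bulk rises did. Of the 100 genes with the largest bulk fall from Ngn3-low to Ngn3-high, 94 lay under 1 CPM in the summed Ngn3-low single cells, and so did 791 of the 3197 genes (24.7%) that fell by at least 2-fold. Of the 100 largest rises 1 lay under 1 CPM in the summed Ngn3-high single cells, and 295 of 2251 (13.1%) of those of at least 2-fold. Glucagon stood apart, with Gcg at 245 and 1012 CPM in the bulk Ngn3-low and Ngn3-high libraries and at 5.69 and 2.27 CPM in the WT single cells of these gates.

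Several more genes rose into Ngn3-high cells and fell after them (edgeR adjusted p under 0.05 in both steps). The transglutaminase gene Tgm7 went from 2.77 ± 0.354 to 271 ± 5.48 and back to 2.40 ± 0.159 CPM across the 3 bulk populations. Its relative Epb4.2, a membrane protein gene of the same family, went from 3.72 ± 0.236 to 168 ± 0.510 and 3.35 CPM. The matrix protein gene Mfap4 went from 9.37 ± 4.51 to 239 ± 47.4 and 3.94 ± 1.86 CPM. Insulin reads of single deleted Ngn3-high cells were highest in number 5, where the log2 ratios to WT were 5.26 for Ins1 and 5.64 for Ins2, against -2.21 and -2.02 in number 1 and 1.19 and 1.60 in number 6. Ins2 stood at 186 CPM in the deleted cells of number 5, 3.09 CPM in number 1 and 7.57 CPM in number 6. Number 5 is also the number with Sst reads in nearly every cell. Such sums can rest on a few cells, and the share of cells with insulin reads is not given here.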
